A study of Homo sapiens with 19 samples.

How the data were processed

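ChIP-seq was done for IR (antibody sc-711, to the beta chain) and Pol II (antibody CST_2629) in HepG2 and SH-SY5Y cells, per the labels. Per the labels' protocols, cells were kept in medium with 10% fetal bovine serum, starvation meant 16 h in 0.1% bovine serum albumin, and insulin was given at 10 nM for 20 min. The protocols are shared by all samples and do not say which samples received insulin. The note on the input shared by replicate 2 speaks of starved and insulin-treated HepG2 samples. Codes in the labels of the starved ChIP libraries share a beginning within each replicate number, so comparisons of starved IR with starved Pol II stay within a code. The other ChIP libraries carry no code, so a batch and starvation cannot be told apart. Replicates are biological replicates from independent experiments, per the labels' protocols. Libraries were made with the ThruPLEX kit. Of the 19 samples, 12 have a peak list, and the 7 input samples are not analysed here.

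Per the submitters' processing notes, FastQC, cutadapt 1.4.2, Bowtie2 2.2.8, MACS2 2.1.1, deepTools and the build hg19 were used, with no role or order given. The deposited lists are named as IDR output, that is, peaks found reproducibly in both replicates. The IDR threshold, filters and any pooling are not given in the sources used here. The deposited files have 3 columns, chromosome, start and end, in base pairs, with no score, height, p-value or count. Line i of both replicate files of a group was the same peak with other boundaries, as tested by overlap of every row pair. Selection on both replicates means that peaks present in only 1 replicate are not seen, so agreement between replicates is built in. List length depends on depth, antibody yield and threshold, none of which is known, and a peak missing from a list is not evidence of no binding. No peak ended beyond an hg19 chromosome.

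Overlaps of at least 1 bp were counted within each replicate number with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and reported as means with SD of 2 replicates. No test across replicates was run. Random placements used bedtools 2.31.1 shuffle within chromosomes, 1000 per list and replicate, with fixed seeds. Wilson intervals of shares and Newcombe intervals of their differences, at 95%, came from statsmodels 0.14.6. Cytobands and hg19 lengths came from the R package circlize 0.4.16, and plots were made with matplotlib 3.10.9. Positions are 1-based and span the boundaries of both replicates. Peaks were ranked by mean width of both replicates because the lists hold no score. The code was tested on simulated data before use. It recovered 100% of planted overlaps in each setting (1611 among 3976 peaks in HepG2, 1167 among 2988 in starved HepG2, 259 among 572 in SH-SY5Y). The other peaks had been placed off Pol II with the same code, so its 0 false overlaps was fixed in advance. The separate check was bedtools, which gave the same numbers under this and the other overlap rules.

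The named peaks follow a rule fixed before the data were examined. Without an annotation of the files' build, it takes the 5 widest peaks per list and up to 5 peaks of each overlap class, by coordinates, and the text names part of these in order of width. The gene table at hand is of another assembly, GRCh38.p14, so no gene or promoter is named, and the planned promoter shares, gene lists and motif counts are not analysed here. Alternatives fixed before the data were examined were coverage of 50% of the peak, the peak centre, a distance of up to 500 bp, the upper 50% by width, chromosomes 1 to 22, lists of equal length by width, placement within 10 kb and each replicate alone. Merged replicate boundaries, ranking by order in the files, shortened HepG2 lists and the alternatives for chromosome shares and for Pol II peaks with and without IR were chosen after seeing the data, as were the choice of chromosomes 19 and X among the planned chromosome counts, the band counts, the overlaps of IR or Pol II across settings other than those between the HepG2 conditions and between HepG2 and SH-SY5Y for the same protein, and the comparison of Pol II peaks with and without IR.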

Results

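Binding of the insulin receptor (IR), a cell-surface receptor tyrosine kinase here immunoprecipitated from nuclei with an antibody to its beta chain, was mapped by ChIP-seq beside that of RNA polymerase II (Pol II) in 2 human cell lines. HepG2 is a liver cancer line and SH-SY5Y a neuroblastoma line. The 12 peak lists fell into 6 groups of 2 biological replicates. These were IR and Pol II in HepG2, IR and Pol II in serum-starved HepG2, and IR and Pol II in SH-SY5Y. Starvation is labelled on 4 of these samples. The treatment of the others is not labelled per sample, so the lists without a starvation label are called HepG2 and SH-SY5Y here, and a difference between HepG2 and starved HepG2 lists is not called an insulin response.

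The IR lists held 3976 peaks in HepG2, 2988 in starved HepG2 and 572 in SH-SY5Y. The Pol II lists were longer, with 21998, 14055 and 1976 peaks. Both replicate files of a group list the same peaks in the same order with different boundaries, so peak number has no replicate error, and 1 HepG2 Pol II peak had identical boundaries in both. All 3976 row pairs of the HepG2 IR list overlapped, as did all pairs of the other lists. Median IR peak widths were 369 and 158 bp in the replicates of HepG2, 215 and 222 bp in starved HepG2, and 214.5 and 141 bp in SH-SY5Y. Median Pol II widths were 359.5 and 589 bp, 252 and 840 bp, and 152.5 and 156 bp. The lists give positions only, with no read count, height or p-value, so the depth behind each peak is unknown. Each share below is the mean of replicate 1 set against replicate 1 and replicate 2 against replicate 2, with the SD over these 2 values. The SD measures boundary differences only, because both files of a group had passed the same selection.

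The first comparison asked where IR binds relative to Pol II. In HepG2, 76.1% ± 0.107 (SD, n = 2) of IR peaks overlapped a Pol II peak, which was 3021 and 3027 peaks in the replicates. In starved HepG2 the share was 63.0% ± 3.36 (SD, n = 2), or 1810 and 1952 peaks. In SH-SY5Y it was 4.11% ± 0.371 (SD, n = 2), or 25 and 22 of 572 peaks. The 95% Wilson intervals of the SH-SY5Y share were 2.98% to 6.37% in replicate 1 and 2.55% to 5.75% in replicate 2. The widest HepG2 IR peak, on chromosome 1 at 10853771 to 10856458 (1p36.22, hg19), overlapped no Pol II peak in either HepG2 condition. The second widest, on chromosome 11 at 2009186 to 2011352 (11p15.5), overlapped Pol II in both. The next 3 by width lay on chromosome 10 at 8091471 to 8093079 (10p14), chromosome 16 at 49889511 to 49891326 (16q12.1) and chromosome 2 at 60780913 to 60782530 (2p16.1). None of these 3 overlapped a HepG2 Pol II peak in either replicate, although the peak at 10p14 overlapped a Pol II peak of SH-SY5Y.

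IR peaks placed at random on their own chromosomes overlapped Pol II at a mean of 1.10% in HepG2, 0.805% in starved HepG2 and 0.0354% in SH-SY5Y. The highest of the 1000 placements per replicate reached 1.66%, 1.64% and 0.524%, so the observed share lay above every placement in all 3 settings. Placing each peak within 10 kb of its own position raised the mean for the replicates to 11.5% and 11.9% in HepG2, 7.14% and 10.5% in starved HepG2, and 0.208% and 0.201% in SH-SY5Y. The observed share was then 6.49 ± 0.139 times the placed one in HepG2, 7.36 ± 1.58 times in starved HepG2 and 20.1 ± 1.39 times in SH-SY5Y (SD, n = 2). These placements describe the lists and give no test between conditions. With both lists at the length of the shorter by width, the IR share was 24.8% in HepG2, 17.7% in starved HepG2 and 0.699% in SH-SY5Y, and at full length the SH-SY5Y share was 1.66% with 50% of the IR peak covered and 6.64% with up to 500 bp allowed.

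**Figure D1:**
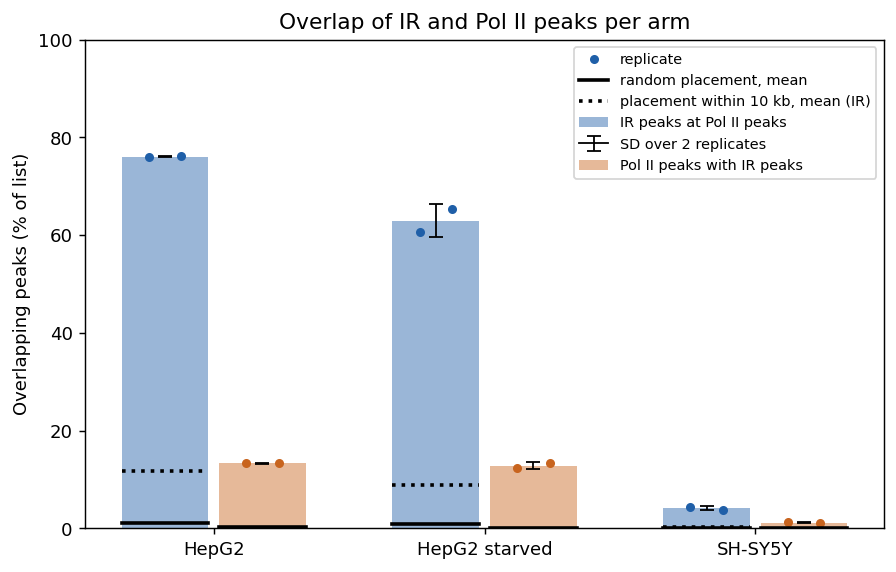
Percent of IR peaks overlapping Pol II peaks (blue) and of Pol II peaks overlapping IR peaks (orange) in each setting. Bars are means of 2 replicates with SD, points are replicates, solid lines mean random placement and dotted lines mean placement within 10 kb. The IR share stands at 76.1% in HepG2, 63.0% in starved HepG2 and 4.11% in SH-SY5Y.

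Seen from the Pol II side, IR peaks marked 13.3% ± 0.0482 of Pol II peaks in HepG2, 12.8% ± 0.664 in starved HepG2 and 1.19% ± 0.107 in SH-SY5Y (SD, n = 2). The HepG2 and starved HepG2 shares differed by less than the boundary spread between starved replicates. Requiring IR to cover 50% of the Pol II peak lowered these shares to 4.40% ± 4.34, 3.35% ± 1.98 and 0.481% ± 0.0358, with the HepG2 replicates far apart, and at equal list length by width they were 22.1%, 15.9% and 0.699%. IR lay more often at wide Pol II peaks in HepG2. The share with IR was 23.7% ± 0.0643 among the widest 10% of Pol II peaks and 2.25% ± 0.289 among the narrowest 10%. In starved HepG2 the same shares were 18.0% ± 0.0503 and 3.24% ± 0.252. In SH-SY5Y no Pol II peak among the 198 widest overlapped IR, and 1.02% of the 197 narrowest did, too few peaks to give a direction. A wider interval also has more room to overlap by chance, and how much of the trend this brings was not separated here. When Pol II peaks were ranked by their order in the files, the first 10% overlapped IR at 46.7% in HepG2, 36.0% in starved HepG2 and 0.253% in SH-SY5Y. What that order stands for is not given in the sources used here, and in HepG2 the median width fell from 709 bp in its first 10% to 394.5 bp in its last 10%. Among the 5 widest HepG2 Pol II peaks, IR peaks lay in those on chromosome 2 at 21239907 to 21267251 (2p24.1), chromosome 20 at 34310721 to 34332455 (20q11.22) and chromosome 8 at 17756863 to 17774530 (8p22). No IR peak lay in the widest, on chromosome 11 at 2660946 to 2699403 (11p15.5), or in that on chromosome X at 133085170 to 133109062 (Xq26.2).

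**Figure D2:**
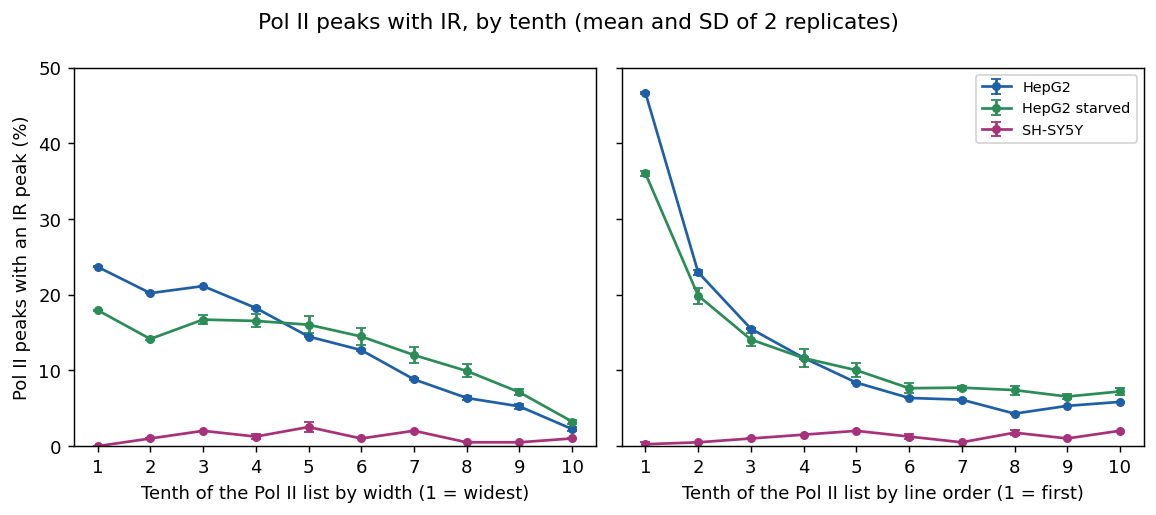
Percent of Pol II peaks with an IR peak (vertical axis) over 10 equal parts of the Pol II list, ranked by width on the left and by order in the files on the right, with means and SD of 2 replicates. By width the share runs from 23.7% to 2.25% in HepG2 and from 18.0% to 3.24% in starved HepG2, and it starts at 0% in SH-SY5Y.

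The second comparison set serum-starved HepG2 against HepG2. Of the starved IR peaks, 71.7% ± 1.30 (SD, n = 2) overlapped a HepG2 IR peak. Of the HepG2 IR peaks, 52.8% ± 0.534 overlapped a starved one. In both replicates 799 starved IR peaks had no HepG2 partner, and 1846 HepG2 IR peaks had no starved partner. Sharing followed rank in the lists. By width, HepG2 IR peaks had a starved partner at 81.0% in the widest 10% and 16.0% in the narrowest. Ranked by order in the files, the shares were 99.0% in the first 10% and 27.7% in the last. For starved IR peaks with a HepG2 partner they were 97.3% and 35.1% by width, and 100% and 47.3% by order. Peaks without a partner were thus more frequent at low ranks and are not read as specific to a condition. The 5 widest peaks of the starved IR list all had a HepG2 partner. They lay on chromosome 11 at 2009602 to 2011337 (11p15.5), chromosome 10 at 8091323 to 8093090 (10p14) and at 6018925 to 6020148 (10p15.1), chromosome 2 at 60781047 to 60782367 (2p16.1) and chromosome 16 at 30933630 to 30934858 (16p11.2). The widest HepG2 IR peaks without a starved partner lay on chromosome 17 at 79949562 to 79951111 (17q25.3) and at 59476404 to 59477962 (17q23.2), and both overlapped Pol II in both HepG2 conditions. The widest starved IR peak without a HepG2 partner lay on chromosome 5 at 64920431 to 64920960 (5q12.3), and overlapped Pol II of either HepG2 condition in 1 replicate.

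HepG2 IR peaks with a starved partner lay at HepG2 Pol II peaks at 75.7% ± 0.279, and those without at 76.4% ± 0.530 (SD, n = 2), a difference close to the boundary spread of the replicates. Of the starved Pol II peaks, 79.4% ± 3.71 overlapped a HepG2 Pol II peak, and 54.1% ± 5.14 of the HepG2 Pol II peaks overlapped a starved one. Starved IR peaks lay at HepG2 Pol II peaks at 72.9% ± 1.18, and HepG2 IR peaks at starved Pol II peaks at 67.8% ± 1.21. HepG2 Pol II peaks with IR were found in the starved Pol II list at 86.7% ± 0.773, against 49.1% ± 5.83 of those without IR. Weighting the latter to the widths of the former gave 63.0% ± 5.52, and weighting them to the order of the former in the files gave 69.0% ± 3.44. Each weighting alone thus left a gap with the boundaries of either replicate. The SD covers boundaries only, and no other error was computed for this gap. In the starved list, 97.7% ± 0.118 of Pol II peaks with IR and 84.2% ± 4.01 of those without, weighted by width, were found in HepG2, or 84.5% ± 2.48 weighted by order. Row partners of the starved Pol II replicates shared a median of 39.6% of their joined length, the least of the 6 groups, and the replicate 1 peak was a median of 0.435 times as wide. In the labels, replicate 2 of every HepG2 group shares an input library, whereas replicate 1 of each group has its own.

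The third comparison set SH-SY5Y against HepG2. Most of the few IR peaks of SH-SY5Y were also HepG2 IR peaks. The share was 74.4% ± 1.61 (SD, n = 2) against HepG2 and 75.9% ± 0.247 against starved HepG2, with random placements at 0.105% and 0.0731%. In both HepG2 lists at once, 69.3% ± 0.865 of SH-SY5Y IR peaks had a partner. In the other direction, 10.6% ± 0.231 of HepG2 IR peaks overlapped an SH-SY5Y one. In both replicates 390 HepG2 IR peaks were present in all 3 IR lists. The widest of these lay on chromosome 16 at 30933671 to 30934987 (16p11.2), chromosome 12 at 133656586 to 133657662 (12q24.33) and chromosome 16 at 30968473 to 30969609 (16p11.2). All 3 overlapped Pol II in both HepG2 conditions and none overlapped Pol II in SH-SY5Y. The widest SH-SY5Y IR peak lay on chromosome 19 at 42746690 to 42747548 (19q13.2) and had partners in both HepG2 IR lists. In neither HepG2 IR list were 19.1% ± 0.989 of SH-SY5Y IR peaks, and the widest of these were on chromosome 6 at 58777074 to 58777918 and at 58778151 to 58779311 (6p11.1), in a band next to the centromere. The second of these was 120 bp wide in replicate 1 and 1161 bp in replicate 2. Whether regions near centromeres were filtered is not given in the sources used here.

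Pol II peaks were shared less between the lines. Of the SH-SY5Y Pol II peaks, 44.9% ± 0.465 overlapped a HepG2 Pol II peak, and 3.61% ± 0.0386 of HepG2 Pol II peaks overlapped an SH-SY5Y one. The widest SH-SY5Y Pol II peak, on chromosome 4 at 174439584 to 174446079 (4q34.1), overlapped no peak of any other list. The second widest, on chromosome 3 at 128202010 to 128207520 (3q21.3), overlapped HepG2 Pol II in both replicates. SH-SY5Y IR peaks lay at HepG2 Pol II peaks at 65.4% ± 1.73, and SH-SY5Y Pol II peaks at HepG2 IR peaks at 21.3% ± 0.823 (SD, n = 2). Against the HepG2 Pol II list shortened to 1976 peaks, as many as in SH-SY5Y, SH-SY5Y IR peaks overlapped at 9.09% when the first peaks in the file were kept and at 5.33% when the widest were kept. With both lists at the length of the shorter by width, sharing between the lines was 24.2% for IR and 14.0% for Pol II.

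**Figure D3:**
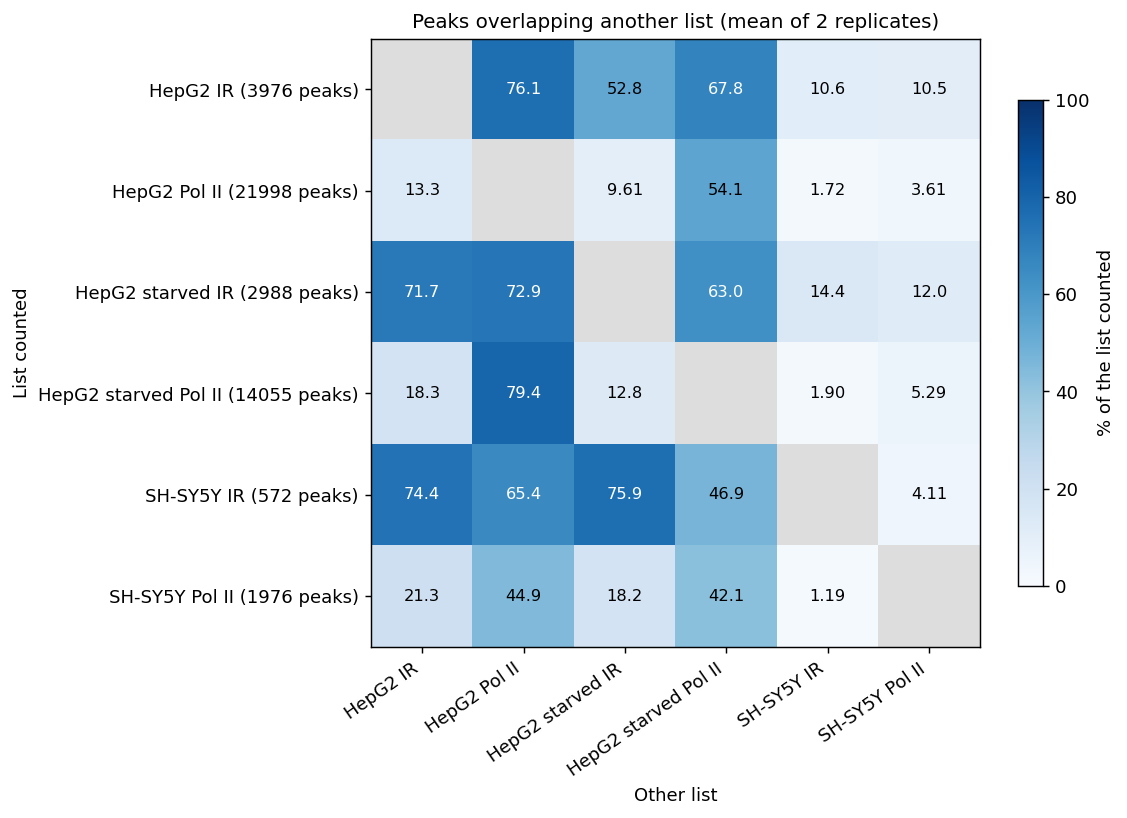
Percent of each list (rows) overlapping each other list (columns), mean of 2 replicates, with list length in the row names. SH-SY5Y IR peaks overlap HepG2 IR at 74.4% and HepG2 Pol II at 65.4%, but SH-SY5Y Pol II at 4.11%.

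The chromosomal distribution of the lists was also compared. Chromosome 19, with 1.91% of the genome length, held 16.8% of SH-SY5Y IR peaks (96 of 572, 95% Wilson interval 13.9% to 20.1%) and 4.86% of SH-SY5Y Pol II peaks (3.99% to 5.90%). In HepG2 it held 6.59% of IR and 7.31% of Pol II peaks, with overlapping intervals and the opposite order in the wider 50% of each list (7.04% and 6.80%), and in starved HepG2 7.999% and 6.44%. Chromosome X held 0.453% of HepG2 IR peaks (18 peaks, 0.287% to 0.715%) and 2.16% of HepG2 Pol II peaks (1.98% to 2.36%). In starved HepG2 the shares on chromosome X were 0.469% and 1.47%, and in SH-SY5Y 0.874% and 0.860%. Among the wider 50% of HepG2 IR peaks, the chromosome X share was 0.101%. Peak centres lay in Giemsa-negative bands, the gene-rich light bands of stained chromosomes, at 57.7% to 68.0% over the 6 lists, and these bands make up 42.2% of the genome length. The intervals cover counting error only, and neighbouring peaks are not independent.

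**Figure D4:**
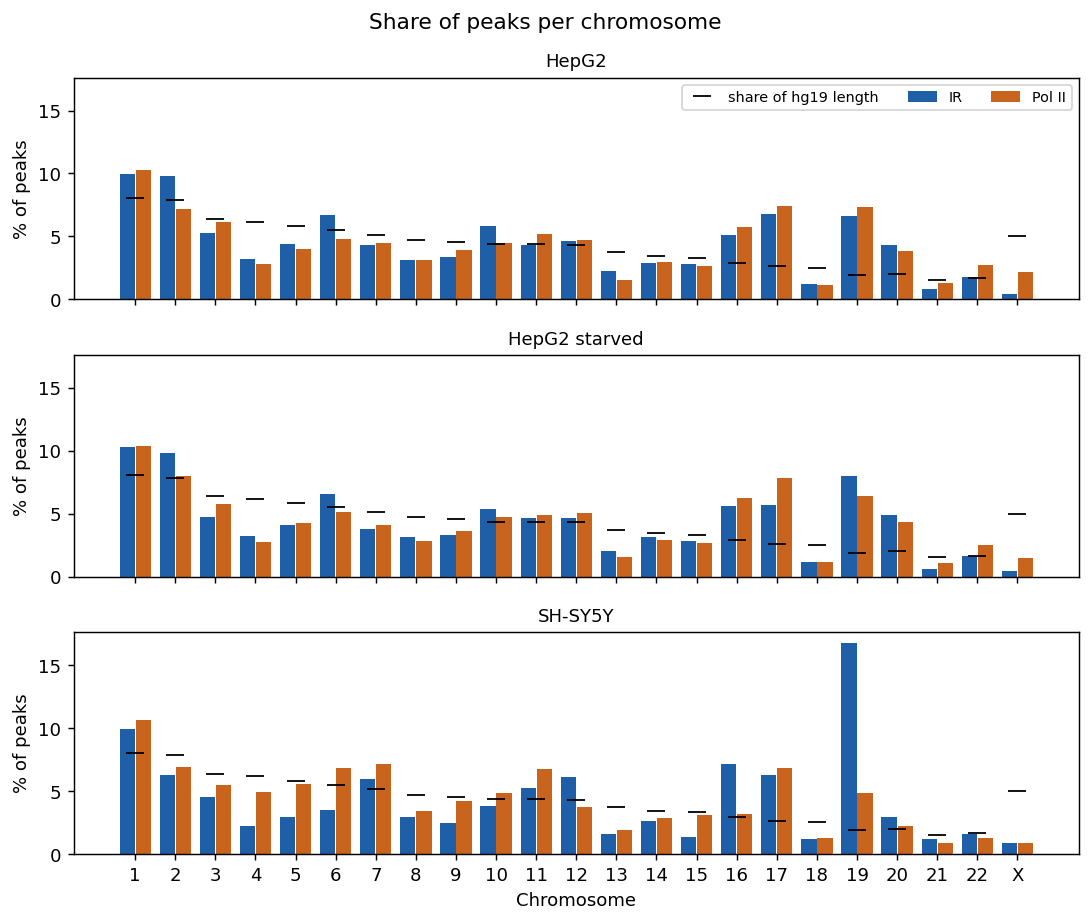
Percent of IR (blue) and Pol II (orange) peaks on each chromosome in each setting, with the chromosome's share of hg19 length as dashes. Chromosome 19 holds 16.8% of the SH-SY5Y IR peaks and 4.86% of the SH-SY5Y Pol II peaks.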

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

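The tests of IR overlap in SH-SY5Y and of chromosome 19 copies were chosen only after the results were seen, as was the use of the HepG2 value's own interval in the other chromosome 19 test. Results are listed here because a difference took opposite signs in different settings. It lay either in how often the widest and the narrowest Pol II peaks carried IR or in the chromosome shares of IR and Pol II. For chromosome 19 the sign also differed between HepG2 and starved HepG2, which are the same cell line. These differences between settings were not tested, and chromosome counts are identical in both replicates by construction.

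IR peaks met Pol II at 4.11% in SH-SY5Y and 76.1% in HepG2, and the widest Pol II peaks carried IR more often than the narrowest by 21.4 percentage points in HepG2 and 14.7 in starved HepG2, with -1.02 in SH-SY5Y, where 25 and 22 Pol II peaks with IR over the whole list are too few to give a direction. A short SH-SY5Y IR list is argued against as the whole cause. The first 572 peaks of the HepG2 IR list lay at Pol II at 78.8% and the 572 widest at 74.2%, both far above the SH-SY5Y intervals. The 572 widest lay below the 76.1% of the whole list. The SD covers boundaries only and no counting interval was computed for these 572, so a small part by width is neither shown nor excluded. A short Pol II list stays open: against 1976 HepG2 Pol II peaks, the share of SH-SY5Y IR peaks was 9.09% by order in the file, above the SH-SY5Y intervals, but 5.33% by width, within them. Shortening both HepG2 lists to the SH-SY5Y lengths left 25.2% by order and 19.1% by width, both above the SH-SY5Y intervals. Keeping the upper peaks of either ranking thus did not by itself bring HepG2 to the SH-SY5Y share. Drawing the same numbers of HepG2 peaks at random, 100 times, gave a mean of 6.92% (4.46% to 9.79%). The upper SH-SY5Y bound of 6.37% lies within that range, so shorter lists without regard to rank stay open. SH-SY5Y IR libraries that are in truth HepG2 cannot be told apart from sites common to both lines, since 74.4% of their peaks are HepG2 IR peaks. SH-SY5Y IR peaks lay at HepG2 Pol II at 65.4%. This was below the first 572 HepG2 IR peaks (78.8%), the 572 widest (74.2%) and starved HepG2 IR (72.9%). With up to 500 bp allowed, the shares were 72.6% for SH-SY5Y IR and 75.6% for starved HepG2 IR, so these values do not decide on a swap. A difference between the cell lines stays open and untested.

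The chromosome 19 share of IR minus that of Pol II was 11.9 percentage points in SH-SY5Y, 1.56 in starved HepG2 and -0.720 in HepG2, where the 95% Newcombe interval of the difference, -1.530 to 0.1605, gives no direction and the sign turned in the upper 50% of the lists, to 0.242 by width and 0.569 by order in the files. More copies of chromosome 19 in SH-SY5Y would be expected to raise its Pol II share too, but this was 4.86%, below the 7.31% of HepG2 with separate intervals. The Pol II lists differ in length (1976 and 21998 peaks) and the share without extra copies is unknown, so copies are not excluded. A short list that keeps the strongest sites stays open. The first 572 HepG2 IR peaks had 11.4% on chromosome 19 (9.02% to 14.2%), under the SH-SY5Y interval but overlapping it, the first 572 starved peaks had 15.2%, within it, and the 572 widest HepG2 peaks had 5.77%. A difference between the cell lines stays open and untested.

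The chromosome X share of IR minus that of Pol II was -1.71 percentage points in HepG2, -1.004 in starved HepG2 and 0.0138 in SH-SY5Y, where 5 IR and 17 Pol II peaks are too few to give a direction and the upper 50% by order in the files gave -0.561. Of the 476 HepG2 Pol II peaks on chromosome X, 13 and 12 overlapped IR in the replicates, or 2.73% (1.60% to 4.62%) and 2.52% (1.45% to 4.35%). Autosomal Pol II peaks carried IR at 13.6% and 13.5% in the replicates. Weighted to the widths of the chromosome X peaks they carried it at 13.7%, and weighted to their order in the files at 10.3%. Width thus left the gap as it was and order narrowed it in part, so neither alone accounts for all of it. Both at once were not weighted. No biological explanation was tested.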

How the results depend on the processing

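The alternatives by order in the files and with merged boundaries, and all those of chromosome shares and of Pol II peaks with and without IR, were chosen after the results were seen. No paired analysis was possible because both replicate files of a group list the same jointly selected peaks, so their values are not independent measurements that a test could use. Within replicate numbers 1 and 2, the share of IR peaks at Pol II was higher in HepG2 than in starved HepG2 by 15.4 and 10.8 percentage points, and that of Pol II peaks with IR differed by 0.995 and -0.0122. Each overlap share of a replicate alone stayed within the SD, as 2 values must. Of the signed differences, those of IR minus Pol II on chromosome 19 in HepG2 turned from -0.720 to 0.242 in the upper 50% by width and 0.569 by order in the files, and that on chromosome X in SH-SY5Y from 0.0138 to -0.561 by order. The cause of the shifts below was not tested, except that a stricter overlap rule leaves fewer partners, and 500 bp of allowance more, by construction. Missing depth and scores keep peaks of different strength from being told apart. The promoter, gene list and motif alternatives were not run, for want of an hg19 annotation and genome here, nor was ranking by score.

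With 50% of the peak covered, the shares were 71.3% for HepG2 IR at Pol II, 57.7% for starved IR at Pol II, 1.66% for SH-SY5Y IR at Pol II, 4.40% for HepG2 Pol II with IR, 3.35% for starved Pol II with IR, 0.481% for SH-SY5Y Pol II with IR, 64.3% for starved IR in HepG2 IR, 72.02% for starved Pol II in HepG2 Pol II and 71.7% for SH-SY5Y IR in HepG2 IR. With the peak centre covered, they were 71.6% for HepG2 IR at Pol II, 57.8% for starved IR at Pol II, 1.75% for SH-SY5Y IR at Pol II, 6.97% for HepG2 Pol II with IR, 6.23% for starved Pol II with IR, 0.506% for SH-SY5Y Pol II with IR, 66.6% for starved IR in HepG2 IR, 72.2% for starved Pol II in HepG2 Pol II and 72.03% for SH-SY5Y IR in HepG2 IR. With up to 500 bp allowed, they were 78.2% for HepG2 IR at Pol II, 66.8% for starved IR at Pol II, 6.64% for SH-SY5Y IR at Pol II, 14.7% for HepG2 Pol II with IR, 14.1% for starved Pol II with IR, 1.92% for SH-SY5Y Pol II with IR, 74.9% for starved IR in HepG2 IR, 85.5% for starved Pol II in HepG2 Pol II, 76.1% for SH-SY5Y IR in HepG2 IR and 46.2% for SH-SY5Y Pol II in HepG2 Pol II. In the wider 50% of each list, they were 62.5% for HepG2 IR at Pol II, 41.6% for starved IR at Pol II, 2.62% for SH-SY5Y IR at Pol II, 11.0% for HepG2 Pol II with IR, 8.55% for starved Pol II with IR, 0.759% for SH-SY5Y Pol II with IR, 85.6% for starved Pol II in HepG2 Pol II, 72.03% for SH-SY5Y IR in HepG2 IR and 35.8% for SH-SY5Y Pol II in HepG2 Pol II. At equal list length by width, they were 24.8% for HepG2 IR at Pol II, 17.7% for starved IR at Pol II, 0.699% for SH-SY5Y IR at Pol II, 22.1% for HepG2 Pol II with IR, 15.9% for starved Pol II with IR, 0.699% for SH-SY5Y Pol II with IR, 63.7% for starved IR in HepG2 IR, 67.1% for starved Pol II in HepG2 Pol II, 24.2% for SH-SY5Y IR in HepG2 IR and 14.0% for SH-SY5Y Pol II in HepG2 Pol II. At equal length by order in the files, they were 38.3% for HepG2 IR at Pol II, 28.3% for starved IR at Pol II, 0.612% for SH-SY5Y IR at Pol II, 37.0% for HepG2 Pol II with IR, 27.1% for starved Pol II with IR, 0.612% for SH-SY5Y Pol II with IR, 61.8% for starved IR in HepG2 IR, 61.5% for starved Pol II in HepG2 Pol II, 43.4% for SH-SY5Y IR in HepG2 IR and 17.5% for SH-SY5Y Pol II in HepG2 Pol II. With merged boundaries, they were 77.1% for HepG2 IR at Pol II, 4.90% for SH-SY5Y IR at Pol II, 13.5% for HepG2 Pol II with IR, 1.42% for SH-SY5Y Pol II with IR and 73.4% for starved IR in HepG2 IR. On chromosomes 1 to 22 alone, HepG2 Pol II with IR moved to 13.6%, and the other 9 overlap shares stayed within their SD. With placement within 10 kb, the observed over placed ratio was 6.49 in HepG2, 7.36 in starved HepG2 and 20.1 in SH-SY5Y, against 69.1, 81.9 and 116 with placement over the chromosome. Ranked by order in the files, the first 10% of Pol II peaks overlapped IR at 46.7% in HepG2, 36.0% in starved HepG2 and 0.253% in SH-SY5Y. Of 226 alternative values of 50 other shares and differences, 163 moved beyond the boundary spread of the replicates or the counting interval, and 3 changed sign.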

Other observations

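The chromosome and band counts below were chosen after the data were seen. Band 6p22.2, which holds part of the major histone gene cluster, had the most peaks of any band in the SH-SY5Y Pol II list, 34 of 1976 or 1.72%. It held 0.0955% of HepG2 Pol II peaks and 0.121% of starved HepG2 Pol II peaks. The band held 0.302% of HepG2 IR peaks, 0.335% of starved HepG2 IR peaks and 0 of 572 SH-SY5Y IR peaks, a list too short to show a difference. Band 3q21.3 held 1.27% of SH-SY5Y Pol II peaks and 0.223% of HepG2 Pol II peaks. Among IR peaks of SH-SY5Y, 19q13.33 had the most of any band, 18 of 572 or 3.15%, against 0.905% in HepG2 and 1.14% in starved HepG2. Band 19q13.43 held 1.92% of SH-SY5Y IR peaks and 0.354% of SH-SY5Y Pol II peaks. Counts per band were made once, from the centres of the joined boundaries of both replicates, so they have no replicate spread.

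HepG2 IR peaks with a starved partner lay at SH-SY5Y Pol II peaks at 15.4% ± 0.249 (SD, n = 2), and those without at 5.04% ± 0.321. HepG2 IR peaks that were also SH-SY5Y IR peaks lay at SH-SY5Y Pol II peaks at 6.76% and 6.25% in the replicates, and the other HepG2 IR peaks at 11.2% and 10.7%, or at 25.2% in both when weighted to the same order in the file. SH-SY5Y Pol II peaks with IR, 25 and 22 in the replicates, were found in the HepG2 Pol II list at 87.2% ± 1.16, and those without at 44.4% ± 0.531. Along the order of the HepG2 Pol II file, where 0 is the start and 100 the end, the median Pol II peak met by IR stood at 17.9 for HepG2 IR, 19.4 for starved HepG2 IR and 29.7 for SH-SY5Y IR.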
